A study of Homo sapiens with 6 samples.

How the data were processed

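RNA-seq libraries of 6 NCI-H69 samples were described in the labels, 3 with a non-targeting guide RNA and 3 with a knockout of SCRMP. Per the labels' protocols, total RNA was isolated with TRIzol and treated with DNase, polyadenylated RNA was captured on oligo(dT) beads, and BGI made libraries that keep the strand and sequenced them on a DNBSEQ-T7 instrument. The labels call the samples biological replicates and place all 6 in a single batch. They do not say how far back the cultures of a group were separate, so the SDs measure the spread between these 3 libraries only.

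HISAT2, StringTie, DESeq2 and the genome build GRCh38 are named per the submitters' processing notes, which give neither versions nor roles. The annotation release and any filter on genes are not given in the sources used here. The authors deposited a table of 17170 genes with Entrez gene numbers and symbols. It holds TPM per library, per the file headers, and each library's TPM sum to the same total over the genes of the table. It holds read counts per library, per the file headers, which are estimated counts rather than whole reads, and 24.0% of them are whole numbers at the precision given. It also holds FPKM per library, per the file headers, with a scaling total that is not given in the sources used here. Because TPM are shares of a fixed total, abundant genes lower the values of all others. The 10 highest genes took 11.2% and the 100 highest 42.8% of TPM. The genes are nearly all protein coding: 17110 matched RefSeq (GRCh38.p14) by gene number, of which 17054 were protein coding and 12 long non-coding, and 60 did not match. RefSeq gave the positions that are printed.

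Columns were given to samples by name only. The names that the labels state for the control columns were found in the header, and 0 of the 3 names stated for knockout columns were. The header has 12 columns of values for 3 further libraries under a prefix, si, that matches no sample or group in the labels. The prefix reads like small interfering RNA, whereas the labels describe a CRISPR/Cas9 knockout. These 12 columns were given to no sample and used in no step. The tests that were fixed before the data were examined, a differential expression fit and gene set tests of knockout against control, were therefore not run. The authors' own normalized counts and group averages were not used either.

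What was computed are levels in the libraries labelled control. A gene was called detected at 1 TPM or more in all 3 libraries, and 10 TPM marked a higher level. Log2 values were log2(TPM + 1), which compresses differences between genes below a few TPM. Replicate libraries were compared by Pearson correlation across genes and by a chi-square of rounded read counts over genes with at least 10 reads in the pair. The 42 gene lists were fixed before the data were examined, and 41 had measured members. For each list the median over genes was taken in each library and is given as mean ± SD, and its median log2 level was placed among 10000 random lists of equal size drawn from all genes (seed 1). Genes are not independent replicates, so no p-value across genes was computed for these lists. Runs of 31 and of 11 neighbouring genes were ranked by their median log2 level over 17098 genes placed on the autosomes and X, against 1000 shuffled gene orders. Tested on simulated data with 17000 genes, the scan of 31 genes found 19 of 20 runs raised 8-fold and 4 of 20 runs raised 2-fold, so it misses most changes of the smaller size.

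The rule for named genes, fixed before the data were examined, takes MIR7-3HG and its annotated neighbours, and always NEUROD1, POU2F3, YAP1, INSM1, DLL3, CHGA, SYP, NCAM1, MYC, MYCL, MYCN, AMBRA1, REST, BCL2, SLFN11 and EZH2. A further gene of the rule is not reported here, and it stays in the counts and medians of its lists. Its other parts need a test between groups and named no gene. The nearest genes with a value are given in place of annotated neighbours without one. Every other named gene, such as the highest members of a list, was chosen after its values were seen.

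The libraries held 20941185, 22309228 and 22477571 estimated reads. The median gene had 304.2 reads, and genes under 1 TPM rest on few reads, so their levels carry a large counting error. Reads of near-identical copies can be assigned to either copy, and the TMSB15, IFITM, HSPA1, XAGE1 and MTRNR2L genes are uncertain for this reason. Ribosomal protein genes and other abundant genes with many pseudogenes can be affected as well. Alternatives were FPKM, estimated reads with a minimum of 10, a minimum of 5 TPM, TPM scaled without ribosomal protein and MTRNR2L genes, and leaving out each library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.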

Results

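The series profiled poly(A) RNA of NCI-H69, an established small cell lung cancer line that grows in suspension and is regarded as neuroendocrine. Per the labels, 3 biological replicates carried a non-targeting guide RNA and 3 carried a CRISPR/Cas9 knockout aimed at the coding sequence of SCRMP, a product of the MIR7-3HG locus. The comparison that this design implies asks which transcripts differ once SCRMP is lost. It was not made. The labels name a column of the deposited table for each sample, and the names of the 3 control columns were found in its header, while 0 of the 3 names given for knockout columns were. The values below therefore describe the 3 libraries labelled control, each as a mean ± SD with n = 3, and no test between groups was run.

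Estimated reads assigned to genes came to 20941185, 22309228 and 22477571 in control replicates 1, 2 and 3. The table has 17170 genes. At least 1 TPM (transcripts per 1000000 transcripts) was reached by 11696, 11617 and 11565 genes in the individual libraries, and by 11418 genes, or 66.5%, in all 3. A mean of at least 10 TPM was reached by 7577 genes, and 636 genes were listed at 0 TPM in all 3 libraries. The median gene had 6.87 TPM and 304.2 estimated reads. Across genes, log2 values of library pairs had Pearson correlations of 0.998 (replicates 1 and 2), 0.997 (1 and 3) and 0.998 (2 and 3), where genes are not independent replicates. Read counts of these pairs differed by more than sampling noise, with a chi-square per degree of freedom of 8.49, 15.8 and 6.18, so there was no sign of a library deposited more than once. This comparison covers counting error only and does not tell separate cultures from repeat libraries of the same RNA. Among genes with at least 10 TPM, the median coefficient of variation was 6.11% and the 90th percentile 13.6%. It was highest for FOS, an immediate early transcription factor, at 40.1% (81.3 TPM ± 32.6).

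MIR7-3HG, the targeted locus, is annotated as a long non-coding RNA gene on chromosome 19, 4769105 to 4772556 (GRCh38.p14, gene number 284424), and the microRNA gene MIR7-3 lies inside it at 4770670 to 4770779. Its transcript level is not analysed here, so no value of the targeted gene checks the genotype labels. The nearest measured genes were DPP9, a dipeptidyl peptidase gene 45263 bp toward lower coordinates, with 32.9 TPM ± 0.734, and FEM1A, 19178 bp toward higher coordinates, with 9.51 TPM ± 0.675. Of 29 measured genes reported elsewhere as direct targets of miR-7, 24 were detected, that is, at 1 TPM or more in all 3 libraries. Their median level was 25.8 TPM ± 1.91. The highest was the cell cycle gene CKS2 (540.4 TPM ± 68.8), followed by the mitochondrial channel VDAC1 (199.8 TPM ± 4.06). The growth factor receptor EGFR stood at 0.633 TPM ± 0.114.

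Neuroendocrine genes were near 0 in the libraries labelled control. Of 24 measured genes on the neuroendocrine side of a published small cell lung cancer score, 5 were detected: CRMP1 (10.1 TPM ± 0.794), KIF1A (9.80 TPM ± 1.12), TMSB15B (9.41 TPM ± 0.340), TMSB15A (7.66 TPM ± 1.25) and SH3GL2 (2.48 TPM ± 0.303). TMSB15A and TMSB15B are near-identical copies, so the split of reads between them is uncertain. On the non-neuroendocrine side of the same score, 17 of 25 genes were detected, a share close to the 66.5% of all genes. The highest were IFITM3 (544.4 TPM ± 29.6), the annexin gene ANXA1 (528.5 TPM ± 17.4) and S100A10 (184.4 TPM ± 15.6), and IFITM3 also shares sequence with its close paralog IFITM2 (100.1 TPM ± 4.86). The mean log2(TPM + 1) was 0.90 ± 0.02 over the neuroendocrine genes and 3.49 ± 0.02 over the others. Their difference was 2.59 ± 0.02, where the SD is between libraries and says nothing of the spread among genes. The quartiles over genes overlapped, from 0.0633 to 0.912 TPM on the neuroendocrine side and from 0.387 to 38.1 TPM on the other. With a minimum of 10 estimated reads in place of 1 TPM, 11 neuroendocrine genes counted as detected.

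**Figure D1:**
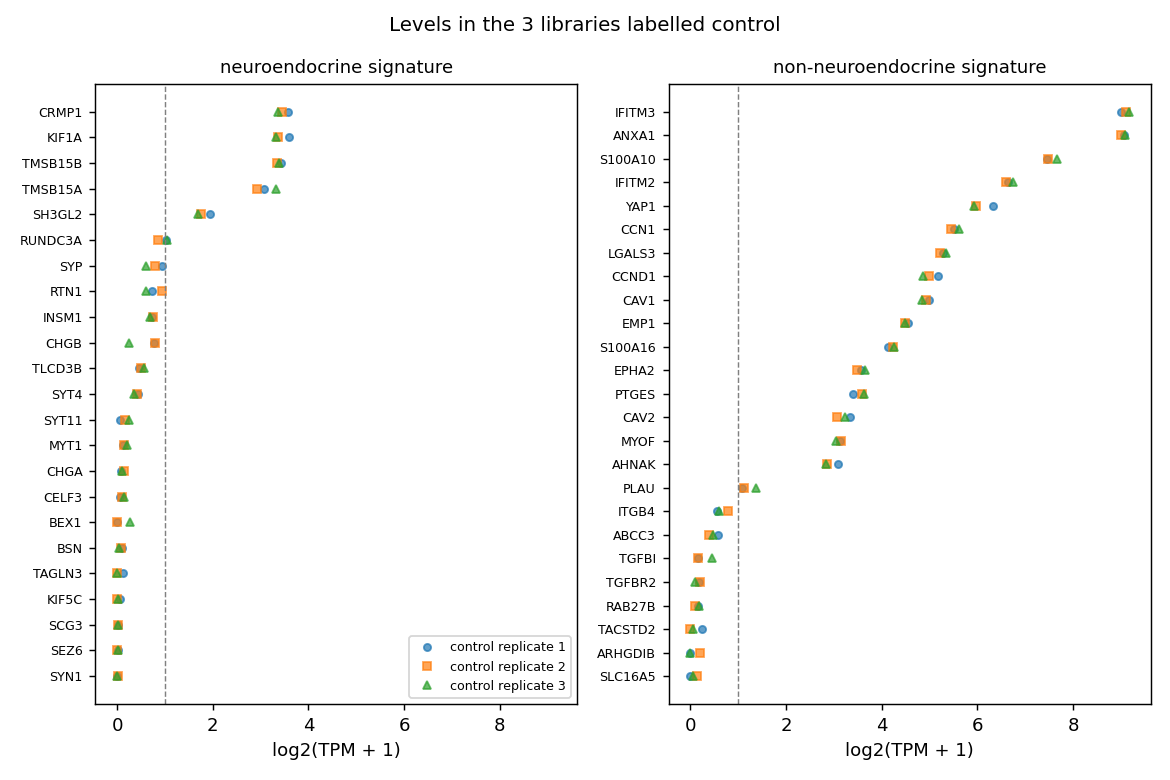
Each point is the log2(TPM + 1) of a gene in 1 of the 3 control libraries (circle, square and triangle), for 23 of the 24 neuroendocrine and all 25 non-neuroendocrine signature genes, and the dashed line marks 1 TPM. In all 3 libraries, 5 genes of the left panel and 17 of the right panel reach the line, and IFITM3 and ANXA1 are highest at 544.4 and 528.5 TPM.

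Single lineage genes ranged from near 0 to moderate levels. INSM1, a zinc finger factor of neuroendocrine cells, had 0.650 TPM ± 0.0458 and the Notch ligand DLL3 0.240 TPM ± 0.0265. The granule protein CHGA had 0.080 TPM ± 0.020 from at most 2 reads per library, and the synaptic vesicle protein SYP 0.717 TPM ± 0.205. NEUROD1 had 0.367 TPM ± 0.186 and POU2F3, the factor of the tuft cell-like subtype, 0.0633 TPM ± 0.0252. NCAM1, the adhesion molecule CD56, was well above these at 25.7 TPM ± 3.66. YAP1, the Hippo pathway co-activator found in non-neuroendocrine disease, had 67.0 TPM ± 10.2 (chromosome 11, 102110447 to 102233424). REST, a repressor of neuronal genes, had 12.6 TPM ± 2.93. Of 19 measured subtype and lineage factors, 5 were detected, with a list median of 0.497 TPM ± 0.0651. YAP1 was the highest, ahead of RCOR2 (38.5 TPM ± 3.29).

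Most lists related to the neuroendocrine phenotype were low as well, and the cell adhesion list was less so. Part of this may come from shared genes. The neuroendocrine signature shares 5 genes with the synaptic list, 3 with the neuropeptide list and 2 with the lineage factor list. Of 15 measured neuropeptide and granule cargo genes, 6 were detected, with a median of 0.633 TPM ± 0.151, although the processing enzymes CPE (123.6 TPM ± 5.06) and PAM (77.5 TPM ± 7.92) were abundant. This list names 24 genes and the tuft cell list 14, of which 8 were measured. Listed genes without a value enter no count, median or percentile, and why they have none is not known. Synaptic vesicle and exocytosis genes had 9 of 21 detected and a median of 0.330 TPM ± 0.0529, and the vesicle protein SV2A had 16.9 TPM ± 0.801. Voltage-gated channel genes had 9 of 29 detected and a median of 0.133 TPM ± 0.0289, and KCNH2 was highest at 25.3 TPM ± 2.88. Neuron projection and cell adhesion genes had 20 of 31 detected and a median of 4.67 TPM ± 0.267, led by the cadherin gene CDH6 (82.0 TPM ± 3.34). Tuft cell markers, which do not mark the neuroendocrine phenotype, had 1 of 8 measured genes detected, IL17RB at 5.25 TPM ± 0.238. The lineage factor list is not limited to that phenotype either, since it holds POU2F3 and YAP1. Against 10000 random lists of equal size drawn from all genes, the medians of the neuroendocrine, synaptic and lineage factor lists lay at percentiles 0.580, 0.750 and 1.76, and those of the tuft cell, voltage-gated channel and neuropeptide lists at 0.520, 0 and 4.0. The neuron projection and cell adhesion list lay at 28.1 and the non-neuroendocrine signature at 75.9. These percentiles describe the control libraries and are not tests.

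Mesenchymal genes were abundant. Of 32 measured members of the mesenchymal list, 27 were detected, with a median of 28.4 TPM ± 1.85. VIM, the intermediate filament vimentin, had 4542 TPM ± 87.8 and was ranked 32 among all genes (chromosome 10, 17228241 to 17237593). The transcription factors TWIST1 and SNAI2 had 320.5 TPM ± 4.86 and 127.2 TPM ± 7.82, and the membrane protease MMP14 had 272.1 TPM ± 2.71. Of 24 epithelial genes, 10 were detected, with a median of 0.703 TPM ± 0.0153. E-cadherin, CDH1, had 0.203 TPM ± 0.0252, EPCAM 0.620 TPM ± 0.249 and KRT18 0.593 TPM ± 0.133, whereas the splicing factor ESRP1 reached 39.4 TPM ± 5.22. Of 17 fibroblast markers, 14 were detected, with a median of 36.9 TPM ± 0.925, led by POSTN (693.8 TPM ± 96.2) and COL3A1 (567.5 TPM ± 19.0). The mesenchymal and fibroblast lists share 2 genes. Leukocyte markers had 3 of 12 detected, with CORO1A highest at 7.49 TPM ± 1.03, and endothelial markers 0 of 8, with ESAM highest at 0.563 TPM ± 0.0839.

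MYC was the dominant member of its family in the libraries labelled control, although MYCN is known as amplified in NCI-H69. MYC had 335.6 TPM ± 14.01 (chromosome 8, 127735434 to 127742951), against 2.79 TPM ± 1.26 for MYCL and 0.203 TPM ± 0.146 for MYCN, which had 2, 9 and 3 reads in the 3 libraries. Of 12 measured family members and partners, 11 were detected, with a median of 17.4 TPM ± 0.320. MAX, the obligate partner, had 119.5 TPM ± 2.93. All 30 MYC targets in ribosome biogenesis were detected, with a median of 75.5 TPM ± 2.24, led by the nucleolar protein gene NPM1 (4823 TPM ± 156). All 43 ribosomal protein genes of the list were detected, with a median of 3272 TPM ± 52.6, and they held 16.1% of all TPM. AMBRA1, an autophagy factor that also promotes turnover of MYC and D-type cyclins, had 19.0 TPM ± 0.731 (chromosome 11, 46396412 to 46594023).

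Proliferation genes were expressed throughout. All 30 genes of G1/S and DNA replication were detected, with a median of 33.0 TPM ± 2.35 and the helicase subunit MCM7 highest at 218.0 TPM ± 6.59. All 30 mitotic genes were detected, with a median of 35.4 TPM ± 2.99 and CDC20 highest at 242.3 TPM ± 11.9. Homologous recombination and Fanconi genes had 27 of 28 detected and a median of 9.42 TPM ± 1.02. The exception was SLFN11, a gene linked to sensitivity to DNA-damaging drugs, which had 1 read in 1 library and 0 in the others. EZH2, the methyltransferase of Polycomb complex PRC2, had 88.1 TPM ± 11.1 (chromosome 7, 148807383 to 148884291). All 29 chromatin regulators were detected, with a median of 13.6 TPM ± 2.20 and SMARCA4 highest at 98.1 TPM ± 3.02. RB1, which is commonly inactivated in small cell lung cancer, had 26.0 TPM ± 1.61, and CDKN2A had 420.2 TPM ± 28.2.

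Genes of several stress responses were abundant. All 30 integrated stress response genes were detected, with a median of 202.2 TPM ± 6.90. The transcription factors ATF4, DDIT3 and ATF3 had 1132 TPM ± 53.6, 925.3 TPM ± 75.5 and 834.5 TPM ± 97.9, and the ATF4 targets TRIB3 and ASNS 1026 TPM ± 86.1 and 876.8 TPM ± 38.6. All 26 genes of the unfolded protein response were detected, with a median of 229 TPM ± 22.3 and the chaperones CALR and HSPA5 at 3119 TPM ± 304 and 2802 TPM ± 243. All 20 heat shock genes were detected, with a median of 272.7 TPM ± 20.99. HSPA1B was given 2363 TPM ± 624 and HSPA1A 2.42 TPM ± 0.772, and these are near-identical copies whose split of reads is uncertain. In the oxidative stress list, 22 of 27 genes were detected, with a median of 77.3 TPM ± 2.49. The iron storage genes FTH1 and FTL had 13779.9 TPM ± 1210.2 and 4067 TPM ± 186, and the heme-degrading enzyme gene HMOX1 had 6052 TPM ± 254. Immediate early genes had 22 of 25 detected and a median of 20.2 TPM ± 5.42.

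**Figure D2:**
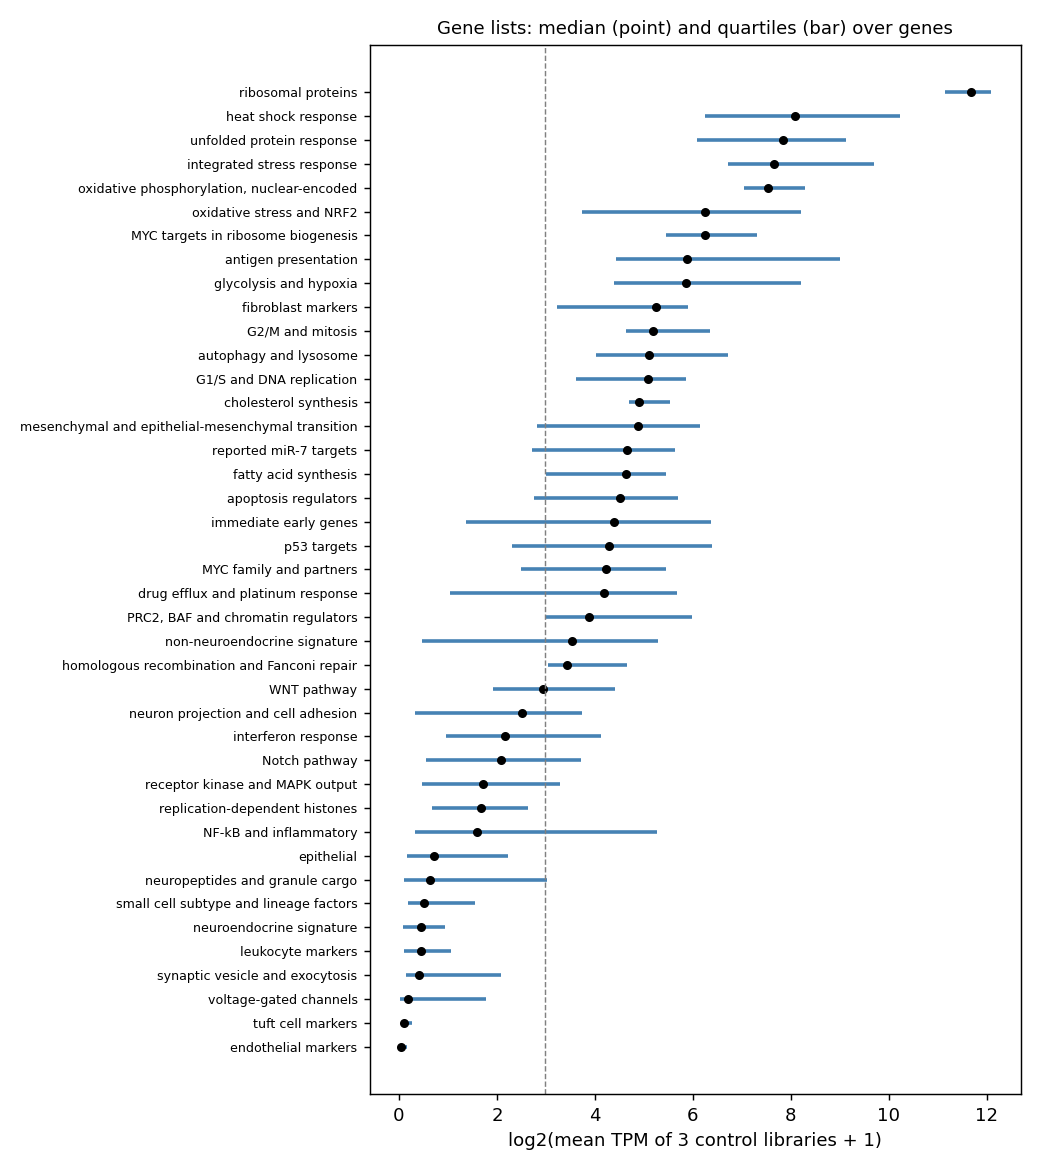
Points give the median over genes, and bars the quartiles, of log2(mean TPM of the 3 control libraries + 1) for the 41 gene lists with measured members, and the dashed line is the median of all 17170 genes. The stress response, respiratory chain and ribosomal protein lists lie at the upper end, and the endothelial, tuft cell and voltage-gated channel lists at the lower end.

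Metabolic and cell survival lists ranged from the respiratory chain to drug response genes. All 38 nuclear-encoded respiratory chain genes were detected, with a median of 183.9 TPM ± 2.14 and ATP5F1B highest at 1925 TPM ± 58.1. Glycolysis and hypoxia genes had 28 of 31 detected and a median of 57.3 TPM ± 5.34, with GAPDH at 11038 TPM ± 681. Cholesterol synthesis genes had 24 of 25 detected and a median of 29.9 TPM ± 0.643, led by SQLE at 329.1 TPM ± 10.9. Fatty acid synthesis genes had 17 of 18 detected and a median of 23.2 TPM ± 1.16. Autophagy and lysosome genes had 35 of 36 detected and a median of 33.3 TPM ± 1.77, with the cargo receptor SQSTM1 at 560.5 TPM ± 46.2. Apoptosis regulators had 28 of 29 detected and a median of 20.7 TPM ± 1.29. BCL2, the anti-apoptotic gene, had 3.79 TPM ± 0.802. Targets of p53 had 20 of 25 detected and a median of 18.4 TPM ± 1.23, with GDF15 at 594.9 TPM ± 27.9. Drug efflux and platinum response genes had 18 of 25 detected and a median of 17.2 TPM ± 0.812, with GSTP1 at 1037 TPM ± 71.3.

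Signalling and immune lists lay on both sides of the median gene. Notch pathway genes had 15 of 23 detected and a median of 3.31 TPM ± 0.0777, led by HES4 (32.9 TPM ± 3.46). WNT pathway genes had 21 of 28 detected and a median of 6.93 TPM ± 1.10. The secreted inhibitor DKK1 had 120.6 TPM ± 26.4 and the pathway targets LEF1 and AXIN2 40.4 TPM ± 1.04 and 36.6 TPM ± 2.89. Taken over the genes' mean levels, the WNT median was 6.62 TPM, which lay -0.05 from that of all genes on the log2 scale, and it moved to the other side, to 0.72 with estimated reads in place of TPM and to 0.02 without control replicate 3. Receptor kinase and MAPK output genes had 15 of 27 detected and a median of 2.30 TPM ± 0.310. Interferon response genes had 22 of 34 detected and a median of 3.53 TPM ± 0.394. The antigen presentation list had 18 of 19 detected and a median of 57.7 TPM ± 1.81, with B2M at 1319 TPM ± 7.62. Its highest gene was the chaperone gene CALR at 3119 TPM. It shares 3 genes, CALR, CANX and PDIA3, with the unfolded protein response list. NF-kB and inflammatory genes had 14 of 24 detected and a median of 2.09 TPM ± 0.243, with the chemokine CCL2 at 539.5 TPM ± 83.1. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, had 20 of 35 detected and a median of 2.12 TPM ± 0.320. The mitochondrially encoded genes are not analysed here. List levels and their order depend on the measure: with estimated reads in place of TPM, 18 of the 41 lists moved by over 1.5 times relative to the median gene.

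Levels along the chromosomes were also examined for the 17098 genes placed on the autosomes and X. The highest running median of 31 neighbouring genes lay on chromosome 8, at 6.66 on the log2(TPM + 1) scale, and the next chromosome reached 5.77.

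**Figure D3:**
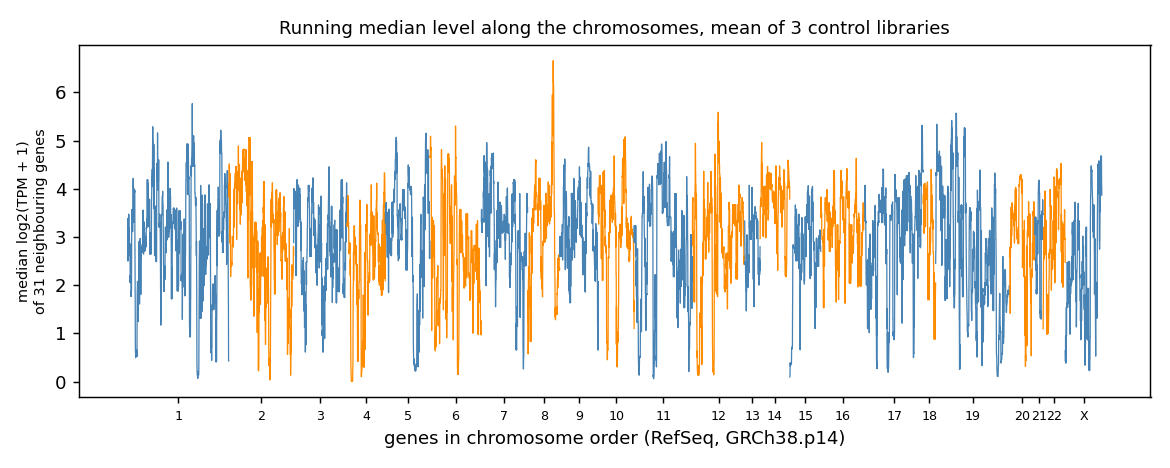
The line gives the running median of log2(mean TPM of the 3 control libraries + 1) over 31 neighbouring genes in chromosome order, with colours alternating between chromosomes. The highest peak, 6.66, lies on chromosome 8, and the highest on any other chromosome, 5.77, on chromosome 1.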

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

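All alternatives given here were chosen after seeing the data, because those planned for the knockout comparison (other normalizations, filters, tools, gene set tests, a block and left-out libraries) could not be run without a column for any knockout sample. No paired analysis was possible because no column matched a knockout sample, although the 2 groups share replicate numbers in the labels. Genes detected in all libraries ranged from 9023 with a minimum of 5 TPM to 12541 with at least 10 estimated reads, against 11418 at 1 TPM. The neuroendocrine genes detected rose from 5 to 11 with estimated reads in place of TPM, since 10 reads are worth less than 1 TPM for most of them, and were 4 to 6 under every other alternative. The non-neuroendocrine genes detected ranged from 16 to 19, against 17. The difference between both signatures was 2.30 with FPKM in place of TPM, 2.69 with estimated reads scaled to equal totals and 2.69 with TPM without ribosomal protein and MTRNR2L genes, against 2.59, and 2.57 to 2.60 without each library in turn. It was positive under each of these. FPKM summed to 566295, 578957 and 587054 in the 3 libraries, less than the TPM total, so the added 1 compresses their log2 differences more. The cause of the other shifts was not tested. Of 245 alternative values for the position of 41 lists against the median of all genes, 243 kept their sign and 2 changed it. Sizes were less stable: relative to the median gene, 18 of 41 lists moved by over 1.5 times with estimated reads, which are not divided by gene length. With FPKM 3 moved, on the log2 scale with 1 added, and 0 moved under the other alternatives. With estimated reads, ribosomal proteins moved from 8.70 to 6.73, respiratory chain genes from 4.55 to 3.31, apoptosis regulators from 1.53 to 0.64, histones from -1.30 to -3.26 and chromatin regulators from 0.89 to 2.07. Both sign changes were of the WNT pathway, at -0.05 in TPM, which moved to 0.72 with estimated reads and lay between -0.060 and 0.024 without each library, with 0.024 without control replicate 3. The cause was not tested. A minimum of 5 TPM leaves levels as they are and gives no value for them. Depth limits statements on genes under 1 TPM: MYCN rests on 2, 9 and 3 reads.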

Other observations

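Highly expressed genes clustered on the long arm of chromosome 8. The highest run of 31 neighbouring genes spanned 119730774 to 125091792 (GRCh38.p14), from TAF2 to WASHC5, with a median log2(TPM + 1) of 6.66, or 100.1 TPM. The highest run on any other chromosome was on chromosome 1, at 5.77. Within or next to the span, NDUFB9, a subunit of respiratory complex I, had 5424 TPM ± 164, TATDN1 1267 TPM ± 48.5, NSMCE2, a SUMO ligase gene, 1327 TPM ± 11.4 and the cholesterol synthesis gene SQLE 329.1 TPM ± 10.9. MYC lies further along the same arm at 127735434. The highest run of 11 genes lay in the same place, 123768439 to 125091792, at 7.74, which 6 of 1000 permutations of the gene order reached (permutation p = 0.007). The highest of these permutations gave 8.52, above the observed run, and the next chromosome, 19, had a run at 7.38.

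Few genes of at least 10 TPM varied by over 1.5 times between the libraries labelled control. The highest library was over 1.5 times the lowest in 110 of 7577 such genes. Smaller differences are not counted here. FOS had 46.8, 85.5 and 111.5 TPM, the inducible chaperone HSPA6 54.7, 116.1 and 77.8 TPM, and the hypoxia-induced lipid droplet gene HILPDA 22.1, 28.4 and 43.8 TPM in replicates 1, 2 and 3. The 10 MTRNR2L genes, nuclear copies that resemble mitochondrial ribosomal RNA and each other, held 1.92%, 1.53% and 1.34% of TPM, and the assignment of their reads is uncertain. The cancer-testis gene MAGEA4 had 155.0 TPM ± 1.57. XAGE1B, another cancer-testis gene, was given 350.1 TPM ± 49.7 and its near-identical copy XAGE1A 267.3 TPM, a split of reads that is uncertain.

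All tests in the following paragraphs were chosen after the result was seen. The first pattern is that neuroendocrine genes were near 0 in libraries labelled as NCI-H69 control. Low TPM made by the authors' normalization to TPM would leave reads near the typical gene, but the median of these genes was 13.3 estimated reads against 304.2 over all genes. An error in assigning reads to genes would lower both, so this covers only the step from reads to TPM. Too little depth is also argued against, since 3 reads, by the ratio of TPM to reads summed over libraries, were worth 0.0834 TPM for the median of all 24 such genes and at most 0.404 TPM. A table or samples of cells other than those labelled also stays open. The 5 of 24 neuroendocrine genes detected define the pattern and so decide nothing. The 0 of 3 knockout column names found and the 12 columns that match no sample go with it. Among random lists, the mesenchymal, fibroblast and epithelial medians lay at percentiles 99.8, 99.6 and 1.53. Lists as unlike as cholesterol synthesis and antigen presentation lay at 99.7 and 99.99, so a high percentile by itself does not mark cell type. Lists of cell type markers did differ, with leukocyte, endothelial and tuft cell markers at 2.99, 0.08 and 0.52, against the high fibroblast markers. The non-neuroendocrine signature lay at 75.9. Not all related values were low: the neuron projection and cell adhesion list lay at 28.1, and CPE had 123.6 TPM. NCI-H69 cells that lost the neuroendocrine state may show the same levels of neuroendocrine, mesenchymal, fibroblast and epithelial genes, though not the column names. MYCN, known as amplified in this line, had 0.203 TPM ± 0.146. An amplified gene can be silenced and no earlier passage was analysed here, so such a loss stays open.

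The second pattern is the run of high genes on chromosome 8. Chance placement is argued against, because 0 of 1000 permutations of the gene order gave a run as high as 6.66. Their highest was 6.11, and the permutation p of 0.001 is the smallest they can give. A gain of the chromosome segment in these cells was not tested by a value that could decide it. The 25 genes of the run at 1 TPM or more had a median of 188.9 TPM, 10.7 times the 17.6 TPM of such genes elsewhere, but the run was picked as the highest, so the ratio says nothing about a gain. A cluster of genes that are highly expressed in most cells is the alternative, and without a reference sample or DNA the explanations cannot be told apart.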
